A study of Mus musculus with 16 samples.

How the data were processed

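RNA of macrophages sorted from mouse muscle as F4/80-positive cells was sequenced in 16 libraries of 4 groups, with 4 libraries in each. The groups were WT and KO, the latter Glud1-deficient per the design text, from normal muscle and from CTX-injected muscle, in which the injected agent is named only by that abbreviation. Per the labels' protocols, RNA was taken with a Qiagen micro kit and amplified with SMART-Seq V4, a full-length cDNA kit that keeps no strand information, so reads of overlapping genes on opposite strands could not be told apart. The deposited values were whole-number counts of reads per gene symbol, not normalized. Per the submitters' processing notes, the tools named were FastQC 0.11.7, cutadapt 1.18, HISAT2 2.1.0 and featureCounts from Subread 1.6.2, with the mm10 genome build. The annotation used for counting and the treatment of reads that map to more than 1 place were not given in the sources used here. Near-identical genes such as Lyz1 and Lyz2 could therefore have gained or lost shared reads.

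The table held 24421 gene symbols, of which 5362 had no read in any library, and each of its sample columns was matched to 1 library by its name. Coordinates were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, where 23376 of the symbols matched a gene name. Library totals ran from 17051892 to 23097420 counts. Amplified reads carry no molecular identifiers, so limits derived from counts cover counting error only. No label says that the libraries came from separate mice, so p-values measure only the spread between these libraries, which may be technical. Pairs of libraries in 1 group differed by more than sampling noise over genes with at least 10 counts, and none was counted as a duplicate. The chi-square per degree of freedom was lowest for WT CTX libraries 1 and 2 (6.02) and KO CTX libraries 3 and 4 (7.31). In the other pairs it was 13.0 to 97.3, and whether the closest libraries are independent was not tested.

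Genes were kept with edgeR's filterByExpr by group, which left 13649, and libraries were scaled with TMM factors. The test was edgeR 4.0.16's quasi-likelihood test with 1 coefficient per group over all 16 libraries and Benjamini-Hochberg adjustment, with a threshold of 0.05, in R 4.3.3. The 4 groups shared 1 estimate of the spread of each gene. A total of 5 comparisons was made: KO against WT in normal muscle, KO against WT in CTX-injected muscle, CTX-injected against normal muscle in WT and in KO, and the difference between the genotype effects (interaction). CPM values were scaled with the TMM factors, except those of Xist, the Y-linked genes and Ifi44l, which used library totals. The prior count of log2 CPM was 2. Single genes were also compared with exact two-sided permutation tests of CPM, whose smallest possible p with 4 against 4 libraries is 0.0286. Shared calls were counted per direction and set beside the number expected for independent lists.

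A set of 34 gene lists was fixed. The study lists were M1, M2, wound healing, and glutamine and glutamate. The programme lists were chemokines, TCA cycle, oxidative phosphorylation, glycolysis, hypoxia, interferon response, proliferation, MHC class II, integrated stress response, cholesterol synthesis, lysosome and lipid handling. The cell type lists were tissue-resident macrophage, monocyte and pan-macrophage, with neutrophil, eosinophil, T and NK cell, B cell, dendritic cell, endothelial, fibroblast, satellite cell and myoblast, muscle fibre, mural cell and erythroid markers for other cells that a sort could carry over. The quality lists were immediate early and heat shock, ribosomal proteins, Y-linked and mitochondrial transcripts. The last could not be scored because none of its 13 genes was among the symbols. Lists with at least 3 tested members were compared with all other genes by camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 33 lists of a comparison. Camera with an estimated correlation, and fry, which asks whether the members of a list move one way on balance, were run beside it.

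Genes named in the text followed a rule. Glud1 was given in every library. Each comparison took the 5 rising and 5 falling genes of largest log2 fold change among those past the threshold whose groups did not overlap and whose mean log2 CPM reached 5 in the higher group, without predicted genes. It also took the 4 members of smallest p of each study list, the member of smallest p of each other list with a call, and all calls where 10 or fewer were made. Some genes that the rule or a call would name are not reported here. The injury comparison in KO could give the values of the genes named in WT in place of its own. The groups, tests, lists, naming rule and most alternatives were set before the data were examined.

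The alternatives set then were size factors of DESeq2 (RLE), the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no low-count filter, a filter of 5 CPM in 4 libraries, a fit of only the groups compared, replicate numbers as a block, and leaving out each library. A further 5 were chosen after seeing the data: library totals as the only scaling, male libraries only, sex as a covariate, leaving out 2 libraries that stood apart in Lyz2, and Lyz2 ratios within same-numbered normal libraries. Sex was read from Y-linked genes with a bound of 10 CPM. The block fits kept only libraries whose number occurs in both groups compared. In normal muscle this left out WT library 6 and KO library 1. Replicate numbers in the sample titles were checked for pairing by correlating deviations from the group means over all tested genes. In normal muscle the same-numbered WT and KO libraries correlated at 0.644, 0.567 and 0.244, all above the bound of 0.1, so the numbers were taken to pair those libraries, although no label says so. The libraries without a partner also correlated with one of the other genotype, WT library 6 with KO library 5 at 0.588 and KO library 1 with WT library 2 at 0.467. Both values exceed the 0.244 of the libraries numbered 5, so the pairing is uncertain. Same-numbered normal libraries were also of the same sex by their counts. WT and KO libraries of opposite sex all correlated negatively (-0.596 to -0.0701). Some male libraries of different numbers did too, at -0.272, -0.27 and -0.202. For the positive values, pairing by number and shared sex cannot be told apart.

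The edgeR test was first checked on simulated counts of known fold changes for every comparison, and DESeq2 and voom, with the same quality weights, for KO against WT in CTX-injected muscle. For KO against WT in normal muscle, edgeR recovered 30% of genes simulated with a 1.5-fold change, 62% at 2-fold and 84% at 4-fold among 13396 genes, with 10 false calls beside 131 true ones over all fold sizes. The shares were 12%, 58% and 80% for KO against WT in CTX-injected muscle over 13517 genes, with 2 false calls. DESeq2 recovered 34%, 62% and 80% of those genes with 16 false calls, and limma voom 14%, 52% and 76% with 4. For edgeR they were 4%, 38% and 70% for the interaction over 13433, with 5 false calls. For the injury comparison they were 18%, 50% and 78% in WT over 13528 genes, with 12 false calls beside 123 true ones, and 28%, 66% and 90% in KO over 13532, with 4 beside 138. With no gene changed, edgeR made 1 false call for the interaction and 0 for each other comparison. The simulated libraries were drawn independently, so structure shared between real libraries was not covered. Each gene's spread was pooled over all 16 libraries, not taken from the groups compared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.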

Results

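Gene expression was measured by RNA sequencing in F4/80-positive macrophages sorted from the muscle of WT and Glud1-deficient (KO) mice, with muscle left undamaged (normal) or taken when damage after CTX injection was greatest. Each of the 4 groups held 4 libraries. Total counts per library were 19352958 to 21903563 in WT and 17051892 to 22521092 in KO normal muscle, and 19842999 to 23097420 in WT and 21222870 to 22230960 in KO CTX-injected muscle. The first principal component separated CTX-injected from normal muscle and held 78.3% of the variance, against 4.88% on the second. Macrophages of normal muscle had 16118 to 16846 detected genes and TMM factors of 1.13 to 1.34, and those of CTX-injected muscle 14434 to 14886 genes and factors of 0.76 to 0.87. Malat1, a nuclear RNA chosen after its values were seen, lay at 869 to 7304 CPM in normal and 745 to 1142 CPM in CTX-injected muscle. These ranges overlapped, and the highest values were those of KO normal library 5 and WT normal library 6 (6966 CPM). WT normal libraries 5 and 6 and KO normal library 5 came from female mice by Xist (104 to 258 CPM) and Y-linked genes (at most 0.103 CPM). The other normal libraries and all 8 from CTX-injected muscle were from males.

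**Figure D1:**
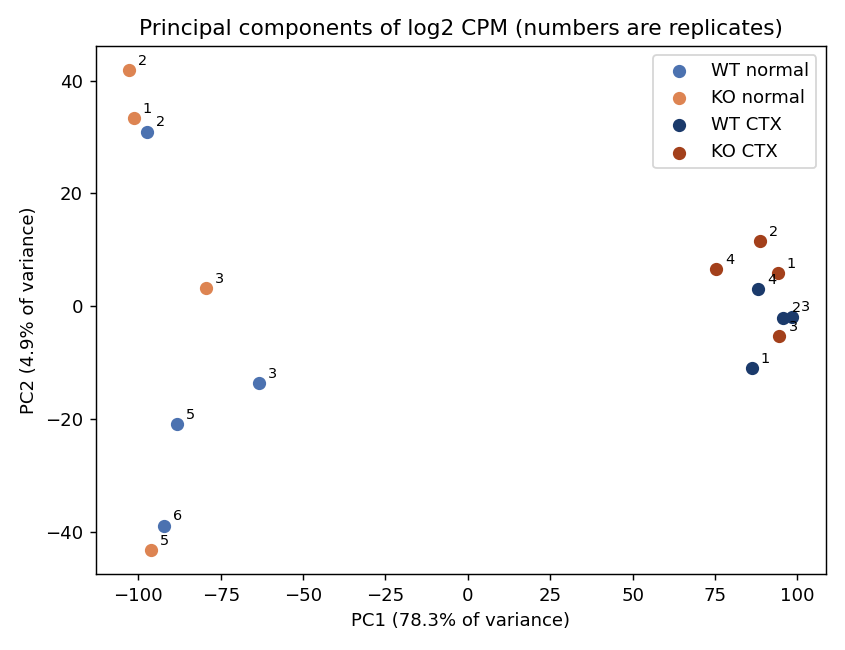
Libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis (78.3% and 4.88%), coloured by group. The 8 normal and the 8 CTX-injected libraries lie apart on the first component, while WT and KO libraries of 1 tissue lie among each other.

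The targeted gene, Glud1, encodes the mitochondrial enzyme that converts glutamate to 2-oxoglutarate and lies on chromosome 14 at 34310727 to 34345265 (plus strand, mm10). Its transcript was at 239.9 ± 25.3 CPM in KO and 256 ± 30.3 CPM in WT normal muscle (SD, n = 4 each), a log2 difference of -0.09 (SE 0.10, edgeR adjusted p = 0.991). In CTX-injected muscle it was at 339 ± 10.5 CPM in KO and 373 ± 19.9 CPM in WT, a log2 difference of -0.14 (edgeR adjusted p = 0.936). Exact permutation tests gave p = 0.486 in normal and p = 0.0571 in CTX-injected muscle. Glud1 read counts therefore did not separate the genotypes. The deleted part of the gene is not given in the sources used here, so a count over the whole gene does not check the labels.

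**Figure D2:**
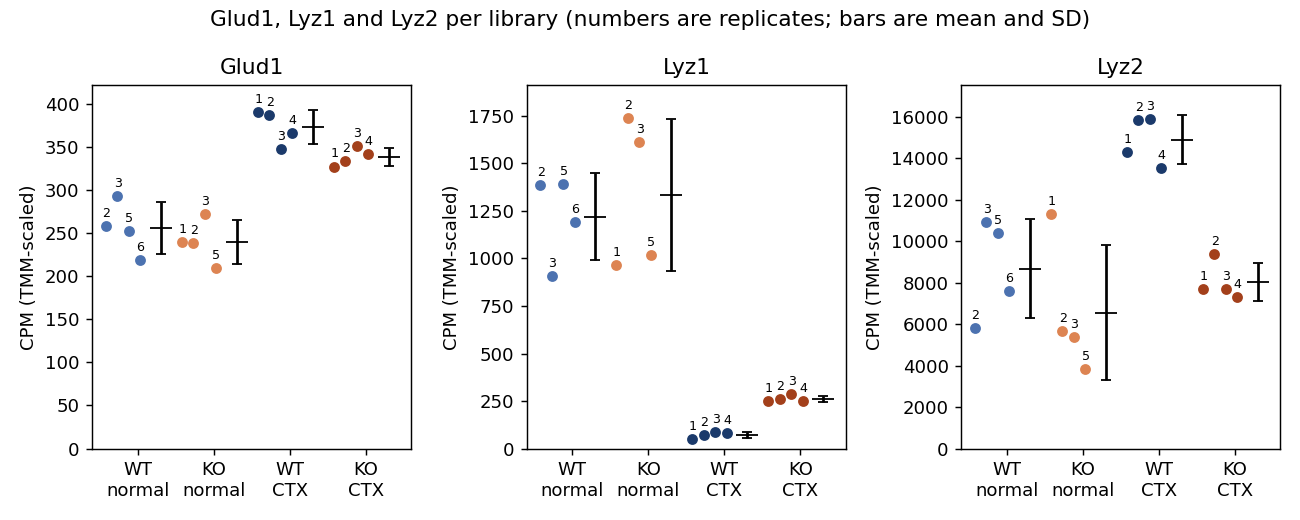
CPM (TMM-scaled) of Glud1, Lyz1 and Lyz2 in each library by group, with points for libraries and the mean and SD of 4. Glud1 overlapped between the genotypes, Lyz1 in CTX-injected muscle was at 262 CPM in KO and 73.7 CPM in WT, and Lyz2 there was at 8021 CPM in KO and 14893 CPM in WT.

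Injury in WT mice addressed how macrophages at the peak of damage differed from those of undamaged muscle. Arg1, the arginase of alternatively activated macrophages, rose from 1.06 ± 0.335 to 1719.5 ± 478 CPM, a log2 change of 10.65 (SE 0.48, n = 4 each). Spp1, which encodes the matrix protein osteopontin, rose from 66.6 ± 71.0 to 9937 ± 1463 CPM. The acute-phase gene Saa3 (log2 10.84), the membrane glycoprotein gene Pdpn (7.37) and Ptges, a prostaglandin E synthase (7.20), completed the largest rises. Among genes whose mean log2 CPM reached 5 in the higher group, the largest falls were in Mamdc2 (34.1 to 0.0702 CPM, log2 -8.76), the lectin gene Siglech (-7.41), the aminopeptidase gene Enpep (-7.25), the sialic acid hydroxylase gene Cmah (-6.92) and Retnla, an alternative-activation gene, which went from 3530.4 ± 1723 to 35.0 ± 14.8 CPM (-6.66), while 7 genes of lower expression fell by more than Mamdc2. Every edgeR adjusted p of these genes was at most 1.15e-05. In all, 4551 genes rose and 5378 fell of 13649 tested by edgeR, 1769 and 3870 of them by at least 2-fold, and 8935 genes had groups that did not overlap (65.5%, against 2.86% by chance). With library totals as the only scaling, which moved the median log2 change by 0.62, the split was 1944 up and 8349 down, so rising genes were 18.9% in place of 45.8% of the calls. With male libraries only, an alternative chosen after the data were seen, 4125 rose and 4888 fell.

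Leaving out single libraries moved several of these folds but ended none of the calls. Saa3 stood at 1428 ± 2439.9 CPM in CTX-injected muscle, and its log2 change was 8.07 without WT CTX library 3, where that of Ptges was 6.31. Without WT normal library 3, the changes were 8.07 for Pdpn, 8.28 for Spp1 and 5.85 for the cystine transporter gene Slc7a11, against 5.13 with it. Mamdc2 was at -9.57 without WT CTX library 1 and Siglech at -8.24 without library 4.

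The study's inflammatory (M1) genes moved both ways with injury in WT. Of 23 measured, 11 rose and 5 fell, among the first the prostaglandin synthase gene Ptgs2 (289 ± 98.2 to 4777 ± 2166 CPM) and the cytokine genes Il1b (885 ± 249 to 4383 ± 2345 CPM), Il1a (log2 3.15) and Il23a (3.09). Of 22 M2 genes 7 rose and 9 fell: the scavenger receptor gene Msr1 (log2 3.20) rose with Arg1, while the lectin gene Mgl2 (548 ± 168 to 9.51 ± 4.34 CPM) fell with Retnla. Of 27 wound healing genes 12 rose and 10 fell. The protease inhibitor gene Timp1 rose from 2.55 ± 1.48 to 174 ± 39.7 CPM and the matrix protease gene Mmp14 by log2 3.76, and the growth factor genes Igf1 (-3.24) and Pdgfb (-2.71) fell. As lists, M1 (mean log2 0.64), M2 (0.01) and wound healing (0.59) were not set apart from other genes by camera (adjusted p = 0.241, 0.980 and 0.541), and the means lay at 0.02, -0.60 and -0.02 with library totals only. The median of the M2 list was -0.25, and its camera direction was down. Counts adjusted over the list alone equalled those over all genes for every list but tissue-resident macrophages.

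Glutamine and glutamate genes rose in 17 of 25 cases and fell in 3 in WT (mean log2 0.75, camera adjusted p = 0.00479; adjusted p = 0.388 with an estimated correlation; mean 0.14 with library totals only, where 8 rose and 5 fell). The amino acid transporter gene Slc7a5 rose from 43.7 ± 6.37 to 146 ± 15.05 CPM, Slc7a11 from 40.3 ± 33.3 to 1409 ± 325 CPM, the asparagine synthetase gene Asns by log2 2.93 and Gclm, a subunit of the glutathione synthesis enzyme, by 2.03. Glud1 rose by 0.54 (edgeR adjusted p = 0.000186) in WT and by 0.50 (0.000406) in KO, but with library totals only its values were -0.07 and -0.11. The integrated stress response list, which shares Asns and Slc7a11, rose in 13 and fell in 1 of 17 genes (mean 1.37, camera adjusted p = 0.00255; adjusted p = 0.388 with an estimated correlation). The gene of smallest p in it, the transcription factor gene Atf3, fell (1508 ± 188 to 377 ± 40.1 CPM).

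By camera, metabolic lists other than cholesterol synthesis were higher in CTX-injected muscle of WT. Glycolysis genes rose in 15 of 16 cases (mean log2 1.52, camera adjusted p = 7.56e-06), among them Pgk1 from 48.5 ± 8.26 to 320 ± 43.6 CPM. Nuclear genes of oxidative phosphorylation rose in 35 of 36 cases (mean 0.92, adjusted p = 1.16e-09 by camera), with the cytochrome c oxidase gene Cox5b at log2 1.17, and HIF targets of the hypoxia list rose in 12 and fell in 2 of 16 (1.12, camera adjusted p = 0.00625), with the oxidase gene Ero1l at 2.43. The adjusted p with an estimated correlation was 0.388, 0.388 and 0.421. With library totals only, the means were 0.90, 0.30 and 0.50, and 12, 20 and 9 genes rose. TCA cycle genes rose in 14 and fell in 4 of 20 cases (mean 0.40, camera adjusted p = 0.00784; adjusted p = 0.490 with an estimated correlation), with the malate dehydrogenase gene Mdh2 at log2 1.53, but with library totals only their mean turned to -0.22 and the call ended (camera adjusted p = 0.0595). Lysosome genes rose in 15 of 20 cases (mean 1.047, or 0.44 with library totals only; camera adjusted p = 3.50e-05; adjusted p = 0.388 with an estimated correlation). Lipid handling genes rose in 7 and fell in 2 of 14 cases (1.12, or 0.51 with library totals only; camera adjusted p = 0.0259; adjusted p = 0.421 with an estimated correlation), with the fatty acid binding protein gene Fabp5 at 3.89. Cholesterol synthesis genes moved both ways, with 6 up and 5 down of 18 (mean -0.02, camera direction up, adjusted p = 0.759; mean -0.64 with library totals only).

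Chemokine genes rose in 10 of 13 cases in WT (mean log2 1.97, camera adjusted p = 0.00288; adjusted p = 0.388 with an estimated correlation), among them Ccl9 from 882 ± 218 to 3936 ± 368 CPM. MHC class II genes fell in 8 of 8 cases (mean -3.35, camera adjusted p = 1.66e-05; adjusted p = 0.388 with an estimated correlation), with H2-Eb1 going from 3379 ± 394 to 329 ± 57.3 CPM. Proliferation genes fell in 22 of 23 cases (-2.41, camera adjusted p = 0.000368; adjusted p = 0.479 with an estimated correlation), with the replication licensing gene Mcm3 at -1.08. Interferon response genes moved both ways, with 3 up and 3 down of 22 (mean 0.18, or -0.44 with library totals only, and camera direction down, adjusted p = 0.949), and Oas1a, an antiviral enzyme gene, rose (1.47).

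Tissue-resident macrophage genes fell with injury in WT in 14 of 16 cases, or 15 adjusted over the list alone (mean log2 -2.48, camera adjusted p = 7.80e-05; adjusted p = 0.388 with an estimated correlation), with the lectin gene Fcna going from 329 ± 116 to 4.48 ± 2.14 CPM. Monocyte genes rose in 4 and fell in 1 of 9 cases (mean 1.20) and were not called as a list (camera adjusted p = 0.1, or 0.0106 with library totals only), with the coagulation factor gene F10 at 4.10. Pan-macrophage genes rose in 10 and fell in 3 of 13 cases (mean 0.54, -0.08 with library totals only; camera adjusted p = 0.0333; adjusted p = 0.388 with an estimated correlation). The Fc receptor gene Fcgr1 among them rose from 48.4 ± 6.14 to 310.3 ± 44.1 CPM. Differences between these lists were not tested.

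Markers of other cell types fell in CTX-injected muscle of WT alongside these groups. T and NK cell genes fell in 12 of 13 cases (mean log2 -4.01, camera adjusted p = 0.00635), dendritic cell genes in 7 of 8 (-3.33, 0.00856; 1 rose), endothelial genes in 10 of 12 (-1.26, 0.00856), fibroblast genes in 9 of 11 (-1.61, 0.0214), mural cell genes in 8 of 8 (-1.78, 0.0167) and muscle fibre genes in 11 of 14 (-2.32, 0.00856). Allowing an estimated correlation gave an adjusted p of 0.433 for T and NK cells and fibroblasts, 0.454 for muscle fibres and 0.388 for the others. With library totals only, which lowered every one of these means, the calls for T and NK cells (camera adjusted p = 0.0893), dendritic cells (0.0692), fibroblasts and muscle fibres (0.0744 each) and mural cells (0.0595) ended. Examples were Cd2 (-3.76), Zbtb46 (-2.91), Eng (-1.62), Col1a1 (-2.78), Myh11 (-3.32) and Ttn (-3.97). Neutrophil genes fell in 7 of 12 cases (mean -2.23, camera adjusted p = 0.418), eosinophil genes in 6 of 7 (-3.83, 0.173) and B cell genes in 4 of 6 (-2.12, 0.139). Among these, Il5ra stood at -3.11, Cd79b at -3.13 and the neutrophil granule gene Ltf at -5.21, or -4.12 without WT normal library 2 and -6.95 without WT CTX library 2. Of 3 satellite cell and myoblast genes 1 rose, Musk (2.58), and 2 fell (mean -0.06, camera adjusted p = 0.817). No erythroid (mean -0.17, camera direction up, adjusted p = 0.941) or Y-linked gene (1.08, 0.323) was called by edgeR, of 3 and 4 tested.

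Immediate early and heat shock genes, which tissue dissociation induces, fell in 15 of 15 cases in WT (mean log2 -2.50, camera adjusted p = 7.56e-06; adjusted p = 0.388 with an estimated correlation), with Nr4a1 going from 1451 ± 196 to 269 ± 49.4 CPM. Ribosomal protein genes rose in 32 of 32 cases (0.85, camera adjusted p = 1.36e-07; adjusted p = 0.433 with an estimated correlation), of which 9 rose with library totals only. No list call of either injury comparison held with an estimated correlation, while fry called 24 lists in WT and 27 in KO. No list call of either ended when a single library was left out.

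**Figure D3:**
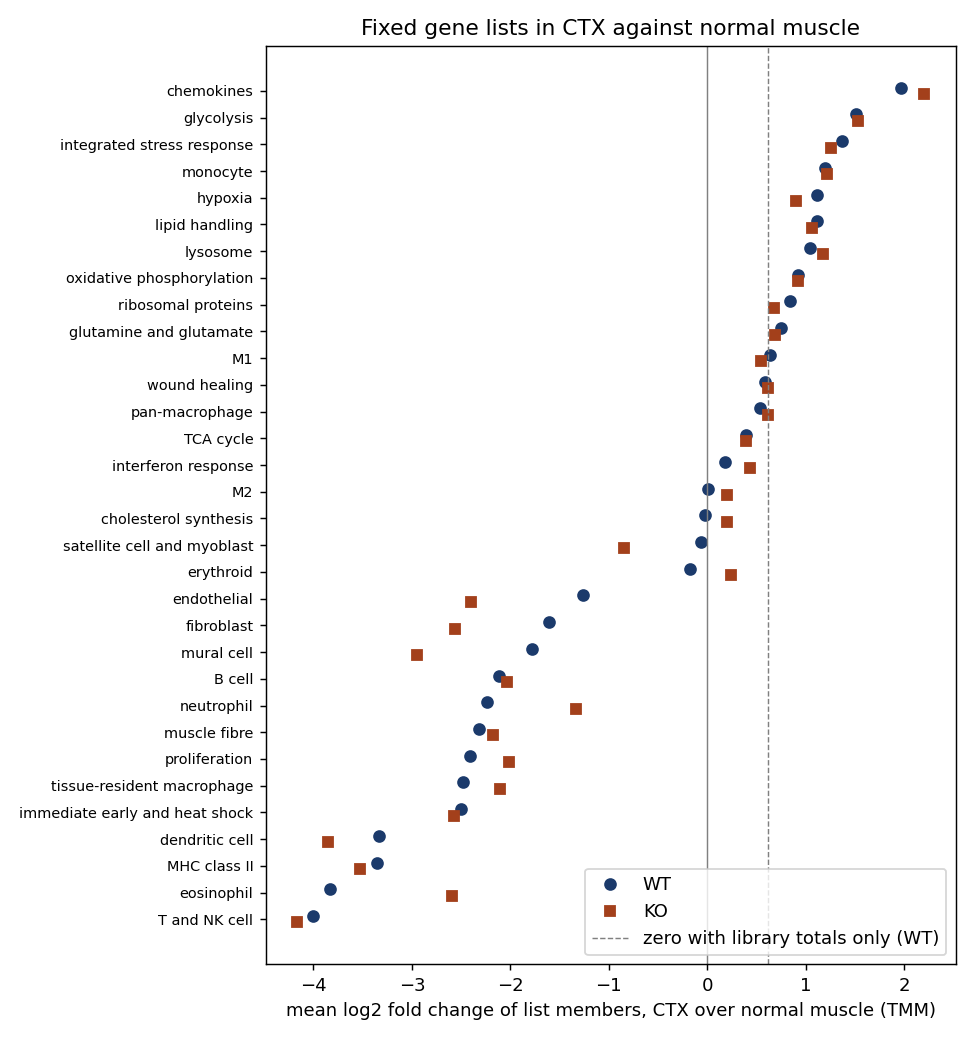
Mean log2 fold change from normal to CTX-injected muscle of each gene list, in WT and in KO, with the dashed line marking where 0 would lie for WT with library totals as the only scaling (shift 0.62). Chemokine (1.97 in WT) and glycolysis genes (1.52) lie to the right and T and NK cell (-4.01) and MHC class II genes (-3.35) to the left in both genotypes, while M2, wound healing, interferon response, TCA cycle and pan-macrophage genes of WT lie on the other side of 0 with that scaling.

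The same injury comparison in KO mice addressed the response of Glud1-deficient macrophages. Arg1 rose from 1.32 ± 0.487 to 2056 ± 1023 CPM and Saa3 from 1.25 ± 1.08 to 393 ± 381 CPM (log2 8.27, n = 4 each). The chemokine genes Ppbp (log2 7.18) and Cxcl3 (34.5 ± 46.5 to 4449 ± 1293 CPM, 7.01) and Pdpn (6.85) followed, among genes whose mean log2 CPM reached 5 in the higher group. Of such genes, the largest falls were in Siglech (-6.79), the receptor gene Adgrg5 (-6.75), Enpep (-6.58), the collagen hydroxylase gene P3h2 (-6.43) and the sulfotransferase gene Sult1a1 (-6.18), and every edgeR adjusted p of these genes was at most 6.16e-05. A total of 66 genes of lower expression, Mamdc2 among them (-7.36, edgeR adjusted p = 2.23e-09), fell by more than Siglech. In all, edgeR called 4549 genes up and 5491 down, 1728 and 3985 of them by at least 2-fold, or 4470 and 5409 with male libraries only. The split was 1920 up and 8398 down with library totals only (shift 0.61; rising genes 18.6% in place of 45.3% of the calls). Saa3 was at 8.87 without KO normal library 1 and 7.495 without KO CTX library 2, where Adgrg5 was at -7.58. Cxcl3 was at 8.63 without KO normal library 3, and Siglech (-7.44) and Sult1a1 (-6.79) moved without KO CTX library 4.

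Of 23 M1 genes 12 rose and 4 fell in KO (mean log2 0.55, camera adjusted p = 0.123; -0.06 with library totals only), among them Ptgs2 (3.24), the formyl peptide receptor gene Fpr2 (2.65) and, falling, the chemokine receptor gene Ccr7 (-2.29). Of 22 M2 genes 10 rose and 8 fell, or 9 adjusted over the list alone (mean 0.20, -0.40 with library totals only; camera adjusted p = 0.705). The transglutaminase gene Tgm2 rose from 275 ± 101 to 2297 ± 321 CPM, and Mgl2 fell (-4.84). Of 27 wound healing genes 11 rose and 10 fell (mean 0.62, camera adjusted p = 0.351), with Timp1 at 6.62, the fibronectin gene Fn1 going from 1567 ± 483 to 8622 ± 1201 CPM and the gelatinase gene Mmp2 at -2.56. Glutamine and glutamate genes rose in 16 and fell in 2 of 25 cases (mean 0.68, camera adjusted p = 0.00385; adjusted p = 0.319 with an estimated correlation), with Slc7a5 at 1.64 and Slc7a11 at 5.08.

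In KO, lists for chemokines (mean log2 2.21), glycolysis (1.53), integrated stress response (1.26), lysosome (1.181), oxidative phosphorylation (0.92), hypoxia (0.90), lipid handling (1.06), TCA cycle (0.40) and pan-macrophage genes (0.62) were higher by camera, with adjusted p from 1.05e-09 to 0.0197. For chemokines, glycolysis, integrated stress response, lysosome and pan-macrophage genes the adjusted p with an estimated correlation was 0.319, and it was 0.361 for oxidative phosphorylation, 0.431 for hypoxia, 0.414 for lipid handling and 0.519 for the TCA cycle. TCA cycle genes turned to -0.21 with library totals only (camera adjusted p = 0.0718), and ribosomal protein genes (mean 0.68, camera adjusted p = 5.37e-06; adjusted p = 0.514 with an estimated correlation) rose in 32 of 32 cases, or 3 with that scaling. MHC class II (-3.53), T and NK cell (-4.16), dendritic cell (-3.85), mural cell (-2.94), fibroblast (-2.57), endothelial (-2.40), muscle fibre (-2.17), tissue-resident macrophage (-2.10), proliferation (-2.01) and immediate early genes (-2.57) were lower by camera, with adjusted p up to 0.0168. With an estimated correlation the adjusted p was 0.431 for T and NK cells and tissue-resident macrophages, 0.519 for muscle fibres, 0.531 for proliferation and 0.319 for the others. With library totals only, the calls for T and NK cells (camera adjusted p = 0.0567) and muscle fibres (0.128) ended. Of 22 interferon genes 8 rose and 2 fell, or 7 and 1 adjusted over the list alone (mean 0.43, -0.19 with library totals only; camera adjusted p = 0.108), and the DNA sensor gene Ifi204 rose (1.72). The only neutrophil gene called, the peroxidase gene Mpo (-2.81, edgeR adjusted p = 0.0341), was lost adjusted over the list alone, where all 11 fibroblast genes fell in place of 10. It was also lost without KO normal library 2 (log2 -1.72, adjusted p = 0.167) and without KO CTX library 2, 3 or 4 (adjusted p = 0.0587, 0.0699 and 0.0618).

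The injury responses of WT and KO were set side by side to ask whether damage changed the same genes in both. Of the genes called by edgeR, 4216 rose in both, 92.6% of those in WT, against 1517 expected for independent lists, and 4895 fell in both against 2164 expected. Only 2 genes were called in opposite directions, 1 each way. Across genes, which are not independent replicates, log2 changes correlated at r = 0.93 and rho = 0.965. The comparisons shared no library.

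KO against WT in normal muscle addressed the effect of Glud1 deficiency at baseline. The M2 genes Mrc1, the mannose receptor, and F13a1, a coagulation factor subunit, were at 1011 ± 112 and 2088 ± 404 CPM in KO against 1468 ± 322 and 3146 ± 873 CPM in WT (log2 -0.54 and -0.59, n = 4 each). Cd163, a haemoglobin scavenger receptor gene, was at 563 ± 130.3 against 823 ± 211 CPM, and the transcription factor gene Irf4 at 67.1 ± 29.1 against 103 ± 33.7 CPM. None of these passed the edgeR test (adjusted p = 0.991). Among M1 genes, Ccr7 was at 201 ± 111 CPM in KO and 120.4 ± 23.6 CPM in WT (log2 0.74), and Cd86 (-0.46), Il1a (-0.53) and Cd40 (-0.24) were lower. Among wound healing genes the log2 differences were -0.47 for the protease gene Mmp9, 0.53 for Mmp12, 0.35 for Mmp2 and -0.82 for Timp1. Among glutamine genes they were -0.18 for the glutamine synthetase gene Glul (104 ± 6.52 against 117 ± 20.99 CPM), -0.17 for the aminotransferase gene Oat and -0.29 for the transporter gene Slc38a2. For all of them the edgeR adjusted p was 0.991.

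By edgeR, 0 of 13649 genes passed the threshold in normal muscle, with 390 at an unadjusted p under 0.05 (2.86%). DESeq2 and limma voom also called 0, and 148 genes had groups that did not overlap (1.08%, against 2.86% by chance). As lists, M2 genes were lower in KO (17 of 22 below 0, mean log2 -0.21, camera adjusted p = 0.00136; adjusted p = 0.359 with an estimated correlation; mean -0.11 without WT normal library 5). Library totals as the only scaling (median shift, TMM minus totals, of -0.08) put the M2 mean at -0.12. The exact permutation test of mean log2 CPM of the M2 list gave p = 0.143. Not called were M1 (mean -0.11, camera adjusted p = 0.236), wound healing (-0.14, 0.0787) and glutamine and glutamate genes (-0.09, 0.0692), all of which camera called with library totals only (-0.03, -0.06 and -0.01, adjusted p = 0.0466, 0.0244 and 0.0333). Without WT normal library 2 or KO normal library 3, camera called wound healing (-0.22 and -0.32, adjusted p = 0.00822 and 0.00243) and glutamine genes lower (-0.13 and -0.19, adjusted p = 0.0214 and 0.00281). Adjusted over the list alone, 0 genes of these 4 lists passed in either genotype comparison.

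Chemokine genes were below 0 in 13 of 13 cases in normal muscle of KO (mean log2 -0.52, camera adjusted p = 1.10e-06; adjusted p = 0.163 with an estimated correlation), 4 of them passing when adjusted over the list alone. The mean was -0.32 without WT normal library 3. Tissue-resident macrophage genes were below 0 in 15 of 16 cases (mean -0.36, camera adjusted p = 3.31e-06; adjusted p = 0.466 with an estimated correlation; mean -0.15 without WT normal library 5). Above 0 were the endothelial genes in 12 of 12 cases (0.48, camera adjusted p = 1.25e-06), mural cell genes in 8 of 8 (0.57, 9.89e-06, 2 passing when adjusted over the list alone) and dendritic cell genes in 8 of 8 (0.57, 0.000384, 1 passing). Their adjusted p with an estimated correlation was 0.163, 0.163 and 0.180, and the mural mean was 0.37 without KO normal library 2. With replicate numbers as a block, a fit without WT normal library 6 and KO normal library 1, these camera calls were kept. Camera then also called oxidative phosphorylation (-0.18, adjusted p = 1.34e-06), lysosome (-0.14, 0.00496), MHC class II (-0.16, 0.00664) and eosinophil genes (-0.70, 0.000448).

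Camera further called T and NK cell (mean log2 1.02), B cell (0.72), fibroblast (0.36) and ribosomal protein genes (0.11) higher and cholesterol synthesis (-0.09), pan-macrophage (-0.12) and muscle fibre genes (-0.35) lower in KO normal muscle. Their adjusted p with an estimated correlation was 0.628, 0.687, 0.628, 0.752, 0.508, 0.466 and 0.728. Each of these calls ended in 3 to 6 of the 8 runs that left out a single normal library. T and NK cells were at 0.87, 0.61 and 0.89 without WT library 3 and KO libraries 1 and 2. B cells were at 0.64, 0.59 and 0.66 without WT libraries 3, 5 and 6 and at 0.48, 0.49 and 0.90 without KO libraries 1, 2 and 3. Fibroblasts were at 0.34 and 0.26 without WT libraries 5 and 6 and at 0.34, 0.31 and 0.25 without KO libraries 1, 2 and 3. Muscle fibre genes were at -0.09 and -0.23 without WT libraries 5 and 6, the females of that group, and at -0.26, -0.24 and -0.19 without KO libraries 1, 2 and 3. Mean log2 CPM of this list was 1.57 in KO library 5, the female one, and -0.13 to 0.11 in the other KO libraries. Pan-macrophage genes were at -0.13, -0.08, -0.06 and -0.07 without WT libraries 2, 3 and 5 and KO library 5. Cholesterol synthesis genes were at -0.04, -0.05 and -0.07 without WT library 2 and KO libraries 1 and 5. Ribosomal protein genes were at 0.05, -0.01 and 0.09 without WT library 6 and KO libraries 1 and 2. Calls that held but moved were B cells at 1.14, muscle fibre at -0.58 and ribosomal proteins at 0.23 without WT library 2, ribosomal proteins at 0.17 without KO library 3, and fibroblasts at 0.58, muscle fibre at -0.96 and ribosomal proteins at 0.24 without KO library 5. With library totals only, the pan-macrophage (-0.04, camera adjusted p = 0.0746) and B cell calls (0.80, 0.170) ended, and the means were -0.01 for cholesterol synthesis and 0.20 for ribosomal proteins. With the block, fibroblast (0.14, camera adjusted p = 0.157), muscle fibre (-0.15, 0.118) and cholesterol synthesis (-0.07, 0.0886) calls ended, and ribosomal protein genes turned to -0.11 (0.00402). That fit also left out WT library 6 and KO library 1, so blocking and their loss cannot be told apart.

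KO against WT in CTX-injected muscle addressed the main question of the design text, the M1, M2 and wound healing genes of Glud1-deficient macrophages at the peak of damage. Lyz1, a lysozyme gene on chromosome 10 (117287797 to 117292868, minus strand), was at 262 ± 16.8 CPM in KO against 73.7 ± 15.6 CPM in WT, 3.55-fold higher (log2 1.83, SE 0.21, n = 4 each, edgeR adjusted p = 0.00228, exact permutation p = 0.0286). In normal muscle it was at 1334 ± 398 CPM in KO and 1220.4 ± 229 CPM in WT. Lyz2, the neighbouring lysozyme gene (117277331 to 117282321, minus strand), chosen after its values were seen, was at 8021 ± 922 CPM in KO against 14893 ± 1174 CPM in WT (log2 -0.89, edgeR adjusted p = 0.466, exact permutation p = 0.0286). Lyz2 passed in a fit of only these groups (-0.87, edgeR adjusted p = 0.0148) and by limma voom (-0.91, adjusted p = 0.0329). The main fit takes 1 spread per gene from all 4 groups. In normal muscle the SD of Lyz2 was larger, at 3262 CPM in KO and 2402 CPM in WT. How the counting treated reads shared by these similar genes was not given in the sources used here.

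Lyz1 was the only call of edgeR, and DESeq2 called 43 genes and limma voom 112, each including Lyz1. On counts simulated for this comparison with 200 changed genes, DESeq2 made 16 false calls beside 127 true ones, limma voom 4 beside 110 and edgeR 2 beside 114, and with no gene changed they made 1, 0 and 0. Simulated libraries were drawn independently, while other splits of the real libraries gave up to 7 calls by edgeR. The simulated rates therefore do not tell how many of the real calls are false. At an unadjusted p under 0.05 there were 910 genes (6.67%), and 782 had groups that did not overlap (5.73%, against 2.86% by chance). Lyz1 passed under every alternative run, at an adjusted p of 0.0231 without WT CTX library 2 and 1.18e-13 by DESeq2. A fit of only these groups also called Dcn, a fibroblast proteoglycan gene (-0.83, edgeR adjusted p = 0.0148), chosen after its values were seen.

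None of the genes named for the study lists passed in CTX-injected muscle (edgeR adjusted p from 0.493 to 0.824). Among M1 genes, Ptgs2 was at 2319 ± 467 CPM in KO and 4777 ± 2166 CPM in WT, Il1b at 2602 ± 444 and 4383 ± 2345 CPM, Ccl5 at 6.52 ± 3.36 and 32.5 ± 57.9 CPM, and the chemokine gene Cxcl9 at 3.87 ± 6.64 and 0.428 ± 0.406 CPM. Among M2 genes the anti-inflammatory cytokine gene Il10 was at 250.1 ± 21.7 against 571 ± 275 CPM (log2 -1.19), with groups that did not overlap, Ccl24 at 298 ± 146 against 155 ± 34.5 CPM (0.94), Cd163 at -0.56 and Mgl2 at 0.61. Among wound healing genes the growth factor gene Areg was at 34.4 ± 3.58 against 81.4 ± 50.7 CPM (-1.24), Vegfa at -0.43, Mmp12 at 0.70 and Mmp2 at -0.51. Among glutamine genes, the transporter gene Slc38a1 was at 228 ± 7.47 against 309 ± 56.1 CPM (-0.44), and the log2 differences of Slc7a5 and the CTP synthase gene Ctps were -0.25 and -0.39.

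As lists, M1 (mean log2 -0.20, camera adjusted p = 0.987), M2 (-0.02, 0.954) and wound healing genes (-0.11, 0.987) were not called in CTX-injected muscle, nor were glutamine and glutamate genes, with 22 of 25 below 0 (-0.15, 0.126). The camera direction of M1 was up against its mean, and without WT CTX library 3 the list was called higher in KO (0.62, camera adjusted p = 0.00266), while glutamine genes were called lower (-0.19, adjusted p = 0.0330). Library totals only (the same shift, here -0.09) turned M2 to 0.07 and put glutamine genes at -0.06. Among the other lists, camera called interferon response genes higher in KO (18 of 22 above 0, mean 0.36, median 0.67, adjusted p = 1.12e-13; adjusted p = 0.436 with an estimated correlation). Ifi44, the member farthest below 0, was at -3.68, a value given after it was seen. Mean log2 CPM of the interferon list was 4.22, 3.82, 6.60 and 5.96 in WT CTX libraries 1 to 4 and 5.82 to 6.24 in KO, a difference of 0.88 between the group means of these log values (exact permutation p = 0.371), against 0.36 for the mean of the fitted fold changes. The latter was 0.11, 0.08 and 0.96 without WT CTX libraries 1, 2 and 3, and the camera call was kept in 8 of 8 omissions. Also higher were proliferation (22 of 23 above 0, 0.62, camera adjusted p = 0.000102), neutrophil (10 of 12, 1.40, 0.000773) and cholesterol synthesis genes (14 of 18, 0.13, 0.0279), with adjusted p = 0.882, 0.830 and 0.735 with an estimated correlation. The proliferation score was 1.40 in KO CTX library 3, below every WT library (1.47 to 2.76), and 2.87 to 2.99 in the other KO libraries (exact permutation p = 0.286). The list difference was 1.03 without WT CTX library 2, and the cholesterol synthesis call ended without WT CTX libraries 1 and 2 (0.09 each) and KO CTX libraries 2 and 3 (0.08 and 0.11), with a mean of 0.22 with library totals only. The neutrophil score was 2.72 in KO CTX library 3 and 5.80 to 6.16 in the other KO libraries, against 2.73 to 4.84 in WT (exact permutation p = 0.229).

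Stromal markers were lower by camera in KO CTX-injected muscle. Endothelial genes were below 0 in 10 of 12 cases (mean log2 -0.66, camera adjusted p = 2.93e-05), with 7 lower and 1 higher when adjusted over the list alone. Fibroblast genes were below 0 in 9 of 11 (-0.60, 0.000102, 4 passing adjusted over the list alone) and mural cell genes in 7 of 8 (-0.60, 0.000514, 1 passing). For these lists the adjusted p with an estimated correlation was 0.373, 0.394 and 0.394. Mean log2 CPM of the endothelial list was 1.97 to 2.45 in WT and 1.55 to 1.94 in KO, and that of the fibroblast list 2.11 to 2.54 and 1.46 to 1.91 (exact permutation p = 0.0286 for each). The mural cell list overlapped, at 0.39 to 1.10 in WT and 0.22 to 0.46 in KO (exact permutation p = 0.0571). Satellite cell and myoblast genes were also called (3 of 3 below 0, -0.62, camera adjusted p = 0.0398; adjusted p = 0.373 with an estimated correlation), a call that ended without WT CTX libraries 1, 2 and 3 (-0.58, -0.62 and -0.53) and KO CTX library 4 (-0.54). No list call of either genotype comparison held with an estimated correlation, and fry called none.

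The interaction asked whether the genotype effect differed between CTX-injected and normal muscle. By edgeR, 0 genes passed, with 646 at an unadjusted p under 0.05, while DESeq2 called 48 and limma voom 11. The smallest edgeR adjusted p, 0.0818, belonged among others to Lyz1 (log2 1.70, SE 0.29). Of M2 genes, the chemokine gene Ccl24 had an interaction of 1.54 (edgeR adjusted p = 0.582), Retnla 1.55, Mgl2 1.01 and the checkpoint ligand gene Pdcd1lg2 -0.82. M1 genes stood at 3.48 for Cxcl9, -2.71 for Ccl5, -0.80 for Ptgs2 and -0.82 for Ccr7. Wound healing genes stood at -0.86 for Mmp2, 0.63 for Mmp9, 0.98 for Tgfb3 and -1.37 for Tgfb2, and glutamine genes at -0.48 for Ctps, 0.49 for the transaminase gene Gpt2, -0.33 for Aldh18a1 and -0.44 for Asns.

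Endothelial genes had the clearest interaction (11 of 12 below 0, mean log2 -1.14, camera adjusted p = 5.87e-11). This was the 1 list call of any comparison that held with an estimated correlation (adjusted p = 0.0487), and 9 of its genes passed when adjusted over the list alone. Mural cell genes (7 of 8 below 0, -1.16, camera adjusted p = 8.80e-09) had 6 such genes and fibroblast genes (11 of 11, -0.96, 4.71e-07) 3. With an estimated correlation their adjusted p was 0.0605 and 0.211, and fry called the endothelial (adjusted p = 0.0222) and mural lists (0.0333). Endothelial genes were at 4.04 in KO and 3.57 in WT normal muscle (mean log2 CPM, exact permutation p = 0.0857). The study lists were not called (M1 -0.09, M2 0.19, wound healing 0.04, glutamine and glutamate -0.06; camera adjusted p = 0.522, 0.0841, 0.399 and 0.891), and the camera direction of M1 was up. Single omissions gave calls for M1 at 0.73 without WT CTX library 3 (camera adjusted p = 0.000647), for M2 at 0.24, 0.28 and 0.26 without WT normal library 2, KO normal library 5 and KO CTX library 2, and for wound healing at 0.24 without KO normal library 3.

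Camera also called interferon response (mean log2 0.25, adjusted p = 8.80e-09), cholesterol synthesis (0.22, 0.000297), tissue-resident macrophage (0.38, 0.000826) and chemokine genes (0.23, 0.0134) in the positive direction, and dendritic cell (-0.52, 0.0143), satellite cell and myoblast (-0.79, 0.0394) and ribosomal protein genes (-0.17, 0.00366) in the negative one. With an estimated correlation the adjusted p was 0.626, 0.227, 0.686, 0.626, 0.458, 0.214 and 0.958. The camera call of interferon genes stayed positive in 16 of 16 omissions, and their median interaction was 0.55. Their mean fitted interaction was 0.85 and 0.40 without WT CTX libraries 3 and 4, was -0.03 without WT CTX library 2 (camera adjusted p = 0.00013) and -0.00 without library 1 (3.52e-05), and was 0.11, 0.40 and 0.16 without WT normal library 6 and KO normal libraries 1 and 3. Tissue-resident genes were at 0.19 without WT normal library 5. The chemokine call ended without WT normal library 3 (0.05), KO normal library 2 (0.10), WT CTX library 4 (0.18) and KO CTX library 1 (0.17), and its mean was 0.39, 0.46 and 0.47 without WT normal library 2, KO normal library 3 and WT CTX library 3. Dendritic cell genes were no longer called without KO normal library 1 (-0.31), WT CTX library 1 (-0.40) and KO CTX library 1 (-0.41). For ribosomal protein genes this was so without WT normal library 6 (-0.08), KO normal libraries 1 and 2 (-0.02 and -0.13) and KO CTX library 4 (-0.13), and their mean was -0.26 and -0.27 without WT normal library 2 and KO normal library 5. The satellite cell call ended in 7 of 16 runs, at -0.76 without WT normal library 2, -0.53 and -0.73 without KO normal libraries 2 and 3, -0.75 and -0.70 without WT CTX libraries 1 and 3, and -0.78 and -0.70 without KO CTX libraries 1 and 4. Between the genotype comparisons, log2 differences correlated across genes at r = -0.02 (rho = 0.0959).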

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

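The tests on Lyz1 and Lyz2, on the libraries that stand apart in Lyz2 and on stromal markers were chosen only after the results were seen, while the splits of the samples were planned.

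Lyz1 was 188 CPM higher and Lyz2 6872 CPM lower in KO than in WT CTX-injected muscle, and a Lyz1 difference of 2.74% of that of Lyz2 argues against reads moved from Lyz2 to Lyz1 for the lower Lyz2 (233 CPM at most against 4133 CPM at least between single libraries). A share of moved reads common to both genotypes is argued against for the higher Lyz1. It would add more reads in WT, where Lyz2 was at 14893 against 8021 CPM in KO, but Lyz1 was only at 52.7 to 88.8 CPM. A share particular to KO stays open: 2.35% of the Lyz2 reads of KO would be enough, a share that gives 154 CPM in normal muscle, where Lyz1 was 114 CPM higher in KO (SE 230, exact permutation p = 0.6). An insertion at Lyz2 carried by the KO mice stays open, and no label names such an allele: the Lyz2 ratio in normal muscle was 0.754 (exact permutation p = 0.314, unpaired), but 0.572 without KO library 1, 0.679 without WT library 2 and 0.515 without both, which were picked for their Lyz2 values. Within the same-numbered pairs 2, 3 and 5 it was 0.977, 0.495 and 0.369 (log2 -0.84 with the replicate block, edgeR adjusted p = 0.647). DNA of another strain near the locus also stays open, with 5.48% of the genes within 10 Mb at an unadjusted p under 0.05 against 6.70% of the other genes (Fisher's exact p = 1), as does an effect of Glud1 deficiency, the biological difference the design names, which was not tested apart from these.

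Lyz2 of WT normal library 2 (5813 CPM) was the lowest of its group, next to the 3840 to 5677 CPM of KO libraries 2, 3 and 5, and KO normal library 1 (11292 CPM) lay above every WT library (at most 10911 CPM). Another share of macrophages is argued against for the KO library, whose pan-macrophage score, a list that contains Lyz2, differed from the other KO libraries by 0.075 (SD 0.09) where Lyz2 differed by 1.20 on the log2 scale. For the WT library it stays open, with a score difference of -0.11 (SD 0.14) against -0.71 for Lyz2. Exchanged labels also stay open: Lyz1 of the WT library was 1.19 times the mean of the other WT libraries and that of the KO library 0.665 times, but Lyz1 overlapped between the genotypes in normal muscle. No biological explanation was tested.

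Endothelial, mural and fibroblast markers were lower in KO than in WT CTX-injected muscle, with mural scores that overlapped (exact permutation p = 0.0571). A lower share of all cells other than macrophages would lower leukocyte markers alike and stays open: the stromal minus leukocyte score was -0.50 ± 1.07 in KO against 1.01 ± 0.35 in WT (SD, n = 4 each; difference -1.51, exact permutation p = 0.0571), but 0.995 in KO library 3, inside the WT range of 0.53 to 1.31. The leukocyte score, a mean of the neutrophil, eosinophil and T and NK cell scores, was higher in KO libraries 1, 2 and 4 (1.89, 2.14 and 2.72) than in WT (0.43 to 1.32). In KO library 3 it was lower (0.23). T and NK cell genes in it were of low expression (-1.41 in KO, -1.88 in WT). Dendritic and B cell genes, not part of it, were at 0.94 and 0.16 in KO against 0.86 and -0.26 in WT. The higher values go against a fall of the lists scored, and do not cover all other cells. Stromal cells carried through the F4/80 sort, which should remove them, are a candidate source: endothelial and fibroblast scores correlated within groups at r = 0.416 (permutation p = 0.244; rho = 0.318, p = 0.294; 1 relation computed; r = 0.171 without KO normal library 5 and WT CTX library 4), which does not decide. Their most abundant genes were at 22.3 CPM in KO and 33.3 CPM in WT for Col3a1, 30.2 and 19.5 CPM for Kdr, 16.7 and 18.5 CPM for Pecam1 and 13.5 and 16.7 CPM for Col1a1. The endothelial, mural and fibroblast lists share no gene with other lists, and an effect of genotype on these cells was not tested.

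Other splits of the same libraries were tested for as many calls. For injury, 1 of 35 splits, the real one, reached 9929 genes in WT and 10040 in KO, with 0 as the highest other. No smaller share is possible with 35 splits, so chance was made less likely but not excluded. Every other split mixed normal and CTX-injected libraries on both sides, which widens the spread within each side. Their counts of 0 therefore do not measure how many calls chance alone would give. For KO against WT in CTX-injected muscle, 5 of 35 splits gave at least the real 1 gene and the highest other gave 7, so chance could not be excluded. In normal muscle, all 35 splits reached the real count of 0, as any split must, and the highest other gave 1881, which points to a structure of the samples. That split set libraries with Rn45s at 0.580% to 0.739% of reads against libraries at 0.837% to 1.68%. Genes detected parted too, at 16118 to 16422 against 16465 to 16846. These values were read after the split was seen, and what the structure reflects was not tested. Of the 8 splits that part the 3 same-numbered pairs as the real one does, the highest other gave 0. For the interaction, 100 of 100 drawn splits reached the real 0, and the highest other gave 545.

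The gap of 1 library to the nearest other, as a share of its group's range, passed Dixon's critical value in 30 of 524 groups, where chance gives about 26.2. In WT normal muscle this held for Ccr7 (0.952), Ccl24 (0.845) and Mgl2 (0.832) in library 5, Gclm in library 3 (0.887) and Tgm2 in library 2 (0.924). In KO normal muscle, library 5 stood apart in Ccl9 (0.892), Cox5b (0.861), Myh11 (0.912) and Dcn (0.832), and in the monocyte (0.947), endothelial (0.892) and muscle fibre scores (0.857). Cd40 stood apart in KO normal library 2 (0.935), and Gclm (0.944), Atf3 (0.920) and Il5ra (0.896) in library 3. In WT CTX-injected muscle, Ccr7 stood apart in library 2 (0.944), Mmp9 (0.905), Mmp14 (0.871) and the chemokine score (0.904) in library 3, and the endothelial score in library 4 (0.961). In KO CTX-injected muscle, this held for Mrc1 (0.854) and P3h2 (0.845) in library 2, Ctps (0.870), Mpo (0.930), and the proliferation (0.924) and neutrophil scores (0.894) in library 3, and Il10 (0.877), Areg (0.914) and the lysosome score (0.886) in library 4.

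The genotype effect differed between CTX-injected and normal muscle by the interaction test with camera for 10 lists. Mean log2 interactions were 0.23 for chemokines, 0.25 for interferon response, 0.22 for cholesterol synthesis, 0.38 for tissue-resident macrophages, -0.52 for dendritic cells, -1.14 for endothelial, -0.96 for fibroblast, -0.79 for satellite cell and myoblast, -1.16 for mural cell and -0.17 for ribosomal protein genes. Of these, the endothelial call alone held with an estimated correlation (adjusted p = 0.0487).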

How the results depend on the processing

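Library totals only, male libraries only, sex as a covariate and leaving out both libraries that stand apart in Lyz2 were tests chosen only after the data were seen. Counts of genes stayed within 1.5-fold, or Glud1 kept its side of the threshold, in 365 recomputed values, and counts moved further in 33. Lists kept their side of the threshold, and the direction of the test where called, in 3305 values. For lists, 165 calls were gained, 203 lost and 4 reversed. A list called in neither run was counted as kept even where the sign of its mean changed. For KO against WT in CTX-injected muscle the count of 1 gene became 43 with DESeq2, 112 with limma voom, 3 with only the groups compared and 2 with male libraries only, and was 1 to 2 when single libraries were left out. The interaction count of 0 became 48 with DESeq2, 11 with voom and 1 with male libraries only, with 0 to 2 in single omissions. With library totals only, the injury change of Glud1 turned to -0.069 in WT and -0.11 in KO, which follows from the scaling shift.

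For KO against WT in normal muscle, glutamine genes were called with DESeq2 (-0.076), voom (-0.16), library totals (-0.0080) and without both Lyz2 libraries (-0.10), wound healing with voom (-0.33), library totals (-0.063) and without both (-0.12), and M1 with library totals (-0.026). The M2 call (-0.21) ended with an estimated correlation (adjusted p = 0.359) and with fry (adjusted p = 0.389). In CTX-injected muscle, glutamine genes were called with voom (-0.18) and with only the groups compared (-0.10). In the interaction, M2 was called with DESeq2 (0.19), voom (0.33) and without both (0.21), and wound healing with voom (0.25). Ranges over single omissions in normal muscle were -0.19 to 0.023 for glutamine and -0.32 to 0.015 for wound healing, in CTX-injected muscle -0.37 to 0.62 for M1 and -0.19 to -0.12 for glutamine, and in the interaction -0.26 to 0.73 for M1, 0.12 to 0.28 for M2 and -0.10 to 0.24 for wound healing. Ribosomal protein genes in normal muscle ran from -0.014 (without KO normal library 1) to 0.24, and oxidative phosphorylation from -0.084 to 0.091 (without KO normal library 5). Except for the scaling, the cause was not tested.

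With the replicate block, counts were 0 in normal muscle, 1 in CTX-injected muscle (Lyz1) and 0 for the interaction, 5658 for injury in WT, from 2 shared numbers, and 8580 in KO, with Glud1 at 0.42 (edgeR adjusted p = 0.253) in WT and 0.41 (0.0357) in KO, and the overlap of injury effects was 5389 genes in place of 9111. These fits used only libraries with a shared number, so an effect of blocking cannot be told apart from fewer libraries. Same-numbered libraries correlated above the bound in normal muscle only. There KO library 5 correlated more with WT library 6 (0.588) than with WT library 5 (0.244), so the pairing is uncertain. The same-numbered libraries of normal muscle also shared their sex. Same-numbered WT and KO libraries of CTX-injected muscle correlated at -0.124 to 0.0046 and those across injury at -0.0569 to 0.0682. The block turned ribosomal protein genes to -0.11 in normal muscle and 0.070 in the interaction, and called glutamine genes at -0.10 in CTX-injected muscle. Beyond the list calls given with the comparison, it changed no call in normal muscle. At this depth, and with a spread pooled over all 16 libraries, 58% of 2-fold changes simulated for CTX-injected muscle were recovered.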

Other observations

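The tests on genes read in some libraries and at 0 in others, with their bounds of 100 reads and 2 libraries, were chosen only after Ifi44l had been seen.

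The genes with the most reads, chosen after their values were seen, differed with injury. Cd74, the invariant chain of MHC class II, took the largest share of reads in normal libraries, apart from KO library 5 where Rn45s, a ribosomal RNA precursor, took 1.68%. In CTX-injected muscle it was Thbs1, a matrix glycoprotein gene, at 2.61% to 4.08%. The 10 genes with the most reads held 7.72% to 9.22% of the reads in normal and 11.5% to 13.2% in CTX-injected muscle.

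Ifi44l, an interferon-inducible gene (chromosome 3, 151758737 to 151762892, minus strand, mm10), had 0 reads in 10 of the 16 libraries, where 3 reads would be 0.130 to 0.176 CPM. It had 243 reads in WT normal library 2, 395, 408 and 355 in KO normal libraries 1, 2 and 3, and 440 and 603 in WT CTX libraries 3 and 4. Its neighbour Ifi44 (151730922 to 151749960, minus strand) had 580, 1264, 1103, 850, 1216 and 1445 reads in those libraries and 0 to 127 in the others. A scan for genes with 0 reads in at least 2 and 100 or more in at least 2 libraries of a tissue found 7 genes in normal muscle, 5 of them Ifi44l, Xist and the Y-linked Eif2s3y, Kdm5d and Uty, and 2 in CTX-injected muscle, Ifi44l and Epx. No explanation was tested.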
